A study of Mus musculus with 9 samples.

How the data were processed

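Total RNA had been extracted with trizol from tibialis anterior muscle of C57BL/6 mice aged 6 months and sequenced on an Illumina instrument. The 9 libraries comprised 3 with a non-targeting siRNA, 3 with construct 5 and 3 with construct 7 against Ubr4. The deposited table, made by the authors with tools named as BWA, STAR and HTSeq on the mouse genome mm9, holds FPKM values for 23231 genes. The versions of those tools and the part each played are not stated. Sequence reads were not used here, and siRNA sequences were not analysed here.

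Depth was recovered from the table: FPKM values of genes with few reads lie on steps whose size gives the product of gene length and library depth. With GENCODE M21 gene lengths for 21323 gene identifiers, 2168 of 3944 low genes gave the same depth, and 72.7% of 51761 values under 50 reads were whole numbers of reads within 0.1 reads. Median depth was 32317623 reads and the largest was 1.55 times the smallest. A single read on a transcript of 1 kilobase corresponds to 0.0219 to 0.0341 FPKM. Recovered reads were used for Poisson intervals and for voom only (10416 tested genes). Correlations of libraries within a group were 0.9848 to 0.993. FPKM totals ranged from 478776 to 532345. In a principal component analysis the first component held 39.8% of the variance, and its scores were -10.67, -6.46 and -9.83 for the controls, 23.75, 16.17 and 8.98 for construct 5 and -14.26, 2.26 and -9.94 for construct 7.

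Of 22501 genes with a value above 0, the 10794 with a mean FPKM of at least 1 over all libraries were tested. log2(FPKM + 1) was modelled over all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with trend and without the robust option). The 4 contrasts were each construct against the controls, the mean of both constructs against the controls, and construct 7 against construct 5. Benjamini-Hochberg adjusted p-values under 0.05 within a contrast were called. Ubr4 was also tested by exact permutation of library labels. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 36 lists, the contrasts, the main test and 11 alternatives were fixed before the data were examined; 33 lists had at least 5 measured members. Another 4 alternatives were added after the data were seen: voom on recovered reads, voom with median-ratio scaling, and median-ratio scaling without construct 5 replicate 1 or without construct 7 replicate 1. The 11 alternatives fixed earlier were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, totals of 1000000, the 6 libraries of a contrast alone, a replicate block, robust spread and weights per library. Each of the 9 libraries was also left out in turn.

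Genes were named by rule. Ubr4 came first, then for each construct the called genes whose libraries all lay on one side of the controls, ranked by absolute log2 change, the first 10 higher and 10 lower (5 of each between constructs). Gene models without a name were skipped, and where a direction had fewer than 5 genes the smallest p-values filled it as values. For each list past its test or with at least 3 called members, up to 4 members with the smallest p were named, along with the 2 most abundant members of cell type lists. Hat1, Rbbp4 and Rbbp7 were always named. The values of some list members named by this rule were withheld and are left out.

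The agreement between constructs was compared with 100 simulations of unchanged groups that share controls. The main test was tested on simulated data with 200 changed genes among 10794 and no correlation between genes: it recovered 72% at an absolute log2 change of 0.5 and 98% at 1, with 7 false calls among 177. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.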

Results

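RNA was sequenced from the tibialis anterior muscle of C57BL/6 mice aged 6 months, after small interfering RNA (siRNA) had been electroporated into the muscle. The 9 libraries formed 3 groups of 3: a non-targeting control siRNA and 2 siRNA constructs against Ubr4, called construct 5 and construct 7 here. Ubr4 encodes a very large E3 ubiquitin ligase that recognises degradation signals at the N-terminus of proteins, and the series concerns ubiquitin ligases that affect muscle fibre size. The deposited table gave FPKM (fragments per kilobase of gene, scaled to library depth) for 23231 genes. Depths recovered from the steps between low FPKM values were 29312120, 32317623 and 31177468 reads in the control libraries. They were 33090872, 45563546 and 30379876 reads with construct 5, and 31853374, 38439928 and 43077404 reads with construct 7. At these depths 3 reads on a transcript of 1 kilobase correspond to 0.066 to 0.102 FPKM, a floor that covers counting error only. Nothing in the labels says that the samples came from separate animals, so every p-value measures the spread between samples. Log2 changes are on the log2(FPKM + 1) scale. Positions are not given because the table was made on mm9 and the annotation at hand is on another build. The strand of the libraries is not stated, so values of overlapping genes are uncertain, as are those of families with near-identical members such as globins, ribosomal proteins and histones.

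Ubr4 transcripts were lower in every library of both siRNA groups than in any control library. Ubr4 (ENSMUSG00000066036) stood at 9.06 ± 1.22 FPKM (mean ± SD, n = 3) in the controls. It stood at 3.38 ± 0.568 FPKM (SD, n = 3) with construct 5, 37.3% of the control mean, and at 2.63 ± 0.412 FPKM (SD, n = 3) with construct 7, 29.1% of it. The library with the fewest Ubr4 reads, construct 7 replicate 1, held 1288 of them (95% exact Poisson interval 1219 to 1360). limma gave a log2 change of -1.20 (SE 0.129, Benjamini-Hochberg adjusted p = 0.0168) with construct 5 and of -1.47 (SE 0.129, adjusted p = 0.00882) with construct 7. The mean of both constructs gave -1.34 (SE 0.112, adjusted p = 0.00574). The exact two-sided permutation test gave p = 0.1 for each construct, the smallest that 3 libraries against 3 allow. For the 6 siRNA libraries against the 3 controls it gave 0.02381, again the smallest possible exact p. The change with construct 7 differed from that with construct 5 by -0.27 (SE 0.129), and limma's test of that difference gave an adjusted p = 0.246. The call with construct 5 was lost with no filter on low values (adjusted p = 0.0523) and without control replicate 2 (adjusted p = 0.0629), control replicate 3 (0.0941) or construct 5 replicate 1 (0.0956), over a range of 0.00321 to 0.0956 for all its alternatives. The call with construct 7 was lost with no filter (0.0976) and without control replicate 2 (0.0598), control replicate 3 (0.0877) or construct 7 replicate 2 (0.0736), over a range of 0.00415 to 0.0976.

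**Figure D1:**
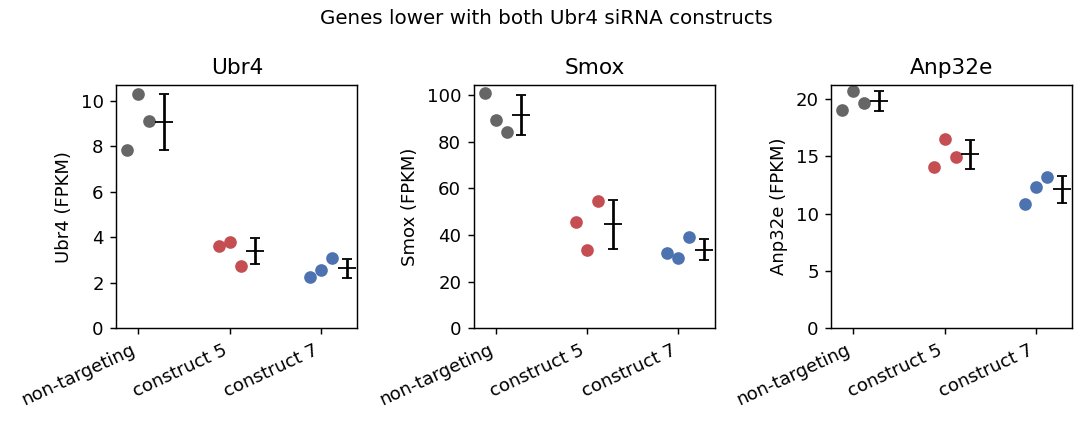
FPKM of Ubr4, Smox and Anp32e in each of the 9 libraries (points), with the mean and SD of the 3 libraries of a group beside them; each axis starts at 0. All siRNA libraries lie below all control libraries in each panel; Ubr4 goes from 9.06 FPKM in the controls to 3.38 with construct 5 and 2.63 with construct 7.

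The first comparison asked which transcripts differed between muscle with construct 5 and muscle with the control siRNA. Sarcolipin (Sln), a small inhibitor of the calcium pump of muscle, went from 10.1 ± 5.24 to 66.3 ± 43.6 FPKM (SD, n = 3), a log2 change of 2.56. Other large increases were in the keratin Krt8 (1.95), the small GTPase Rrad (1.89), the cell cycle inhibitor Cdkn1a (1.42), galectin 3 (Lgals3, 1.36) and the stress-response gene Gadd45a (1.02). The detoxifying enzymes Aldh3a1 (2.28) and Nqo1 (1.13), the tendon and corneal proteoglycan Kera (1.12) and Trdj1 (3.03), a short joining segment of a T-cell receptor locus, rose as well. Trdj1 stood at 0, 1.82 and 0 FPKM in the controls. On a segment far shorter than 1 kilobase each read counts for more FPKM, so its change may rest on few reads. Ube2e1, a ubiquitin-conjugating enzyme, fell from 13.4 ± 0.217 to 7.98 ± 0.133 FPKM (SD, n = 3; log2 change -0.68, adjusted p = 0.00631), and spermine oxidase (Smox) fell from 91.4 ± 8.58 to 44.5 ± 10.5 FPKM (-1.04, adjusted p = 0.0406).

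Further decreases were in the immunoglobulin heavy chain Ighm (-1.13), the cadherin Cdh4 (-0.96), the mitochondrial tRNA mt-Tm (-0.83) and Mccc2 (-0.73), an enzyme of leucine breakdown. Yjefn3 (-0.67), the elongation factor kinase Eef2k (-0.66) and Tulp4 (-0.63) fell too. Each gene named so far for construct 5 lay outside the control range in 3 of 3 libraries, with limma adjusted p-values from 0.00631 to 0.0498. limma called 569 of 10794 genes at an adjusted p under 0.05, of which 504 were higher and 65 lower; 3447 genes passed at an unadjusted p under 0.05, and voom on recovered reads called 629. The groups did not overlap in 4120 genes (38.2%), against 10% by chance. The median of all tested genes lay 0.13 above the controls, and after median-ratio scaling the calls were 78, of which 14 were higher and 64 lower and 65 were among the 569. In that scaling Trdj1, Nqo1, Kera, Ubr4, Smox, Cdh4, mt-Tm, Ube2e1, Eef2k and Tulp4 kept their calls, and the other named genes had adjusted p-values from 0.0505 to 0.076 with no change of direction. The count was 4 without control replicate 1, 4 without control replicate 2, 2 without control replicate 3, 1 without construct 5 replicate 1, 41 without construct 5 replicate 2, 356 without construct 7 replicate 1 and 6 without construct 7 replicate 3. The gene left without construct 5 replicate 1 was Ube2e1, whose call held in all 24 alternatives (adjusted p from 0.00131 to 0.0494).

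Macrophage, matrix and tendon lists were higher relative to other genes with construct 5, each with 2 or 3 members passing the gene test. All 18 measured macrophage markers had values above 0, with a median log2 change of 0.78 and a mean 0.63 above that of all genes (camera adjusted p = 0.00035; adjusted p = 0.85 with an estimated correlation). Gpnmb (0.97), Lgals3 (1.36) and lysozyme (Lyz2, 0.90) passed the gene test, Laptm5 had 0.72 (adjusted p = 0.0601), and 15 passed when adjusted over the list alone; the abundant C1qb went from 16.0 ± 3.13 to 30.4 ± 10.3 FPKM (SD, n = 3; adjusted p = 0.0939). Of 26 fibroblast and extracellular matrix genes, 25 had values above 0 (median 0.42, adjusted p = 0.00144; adjusted p = 0.85 with an estimated correlation). Thbs2 (0.52), collagen Col1a2 (0.61) and osteopontin (Spp1, 0.79) passed, Col1a1 had 0.69 (adjusted p = 0.0557), 13 passed when adjusted over the list alone, and the abundant Sparc (0.31, adjusted p = 0.196) and Dcn (0.21, adjusted p = 0.42) did not pass. The 10 tendon and cartilage markers had a median of 0.96 (adjusted p = 0.00377; adjusted p = 0.85 with an estimated correlation). Kera and Comp (0.96) passed, 7 passed when adjusted over the list alone, and the abundant Thbs4 (1.01, adjusted p = 0.0632) and Cilp (1.19, adjusted p = 0.149) did not pass, nor did Cilp2 (0.58, adjusted p = 0.0754). With median-ratio scaling 0 macrophage genes, 0 matrix genes and 1 tendon gene (Kera) passed, with adjusted p-values of 0.0644 to 0.0923 for the 3 macrophage genes, 0.0874 to 0.111 for the 3 matrix genes and 0.0525 for Comp. The 15 endothelial markers were low relative to other genes (adjusted p = 0.0281; adjusted p = 0.85 with an estimated correlation), although their own median was 0.02 and none passed. Kdr had -0.14, Flt1 -0.10, Egfl7 0.12 and Ramp2 0.07, and the abundant Cdh5 had -0.04 and Pecam1 0.00; with median-ratio scaling Egfl7, Ramp2, Cdh5 and Pecam1 were all below 0.

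Lists of protein turnover, histone chaperones, ribosomes and the interferon response had positive medians with construct 5, beside a median of 0.13 for all genes. With median-ratio scaling the medians were 0.016 for autophagy, 0.03 for ribosome biogenesis, 0.069 for atrophy, 0.094 for histone chaperone and 0.285 for interferon genes. The list of 26S proteasome subunits, with 32 measured, had a median of 0.18 (camera adjusted p = 0.00906, and 0.85 with an estimated correlation). As deposited 22 of the 32 lay above the median of all genes, and with median-ratio scaling the median of the list was 0.035. Psma1 (0.37), Psmc6 (0.38), Psma2 (0.28) and Psma5 (0.40) passed, and 12 passed when adjusted over the list alone; with median-ratio scaling these 4 genes had adjusted p-values from 0.0965 to 0.183 and 0 of the list passed. All 10 members of the list of histone acetyltransferase 1 and histone chaperones had values above 0, and 8 lay above the median of all genes. Their median was 0.22 (camera adjusted p = 0.0221, and 0.85 with an estimated correlation), and 6 passed when adjusted over the list alone. The histone-binding proteins Rbbp4 (0.36, adjusted p = 0.0427) and Rbbp7 (0.31, adjusted p = 0.0471) passed, but not with median-ratio scaling (0.109 and 0.175), while Hat1 itself had 0.13 (adjusted p = 0.313), Ipo4 0.29 (0.0579) and Supt16h 0.24 (0.0799). Ribosome biogenesis genes had a median of 0.15 (adjusted p = 0.0362; adjusted p = 0.85 with an estimated correlation). Nop58 (0.37), Npm1 (0.41), Rrs1 (0.28) and Ddx21 (0.30) passed, and 5 of 23 passed when adjusted over the list alone; with median-ratio scaling these 4 genes had adjusted p-values from 0.0946 to 0.183 and 0 of the list passed. Of the 50 cytosolic ribosomal proteins and translation factors, 49 had values above 0, but only 32 lay above the median of all genes, and 0 passed. Their median was 0.15 (camera adjusted p = 0.0266, and 0.85 with an estimated correlation), and 0.00 with median-ratio scaling. Rpl22 (0.26, adjusted p = 0.0598), Eef1b2 (0.29), Rps23 (0.24) and Rpl5 (0.21) had the smallest p. The 21 interferon response genes had a median of 0.37 with 0 passing (adjusted p = 0.0129; adjusted p = 0.85 with an estimated correlation), Eif2ak2 (0.35, adjusted p = 0.0806), Psmb9 (0.34), Irf9 (0.34) and Stat2 (0.51) having the smallest p. Among atrophy genes, 5 of 21 passed, such as the muscle ubiquitin ligase Trim63 (0.48), Eif4ebp1 (0.53), Gadd45a and Cdkn1a, and 9 passed when adjusted over the list alone. Among autophagy and lysosome genes, 4 of 24 passed, such as Lamp2 (0.33), Atg12 (0.42) and Sqstm1 (0.50), and 6 passed when adjusted over the list alone. With median-ratio scaling 0 genes of both lists passed. Neither of these lists passed as a list (camera adjusted p = 0.27 and 0.482).

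Genes of energy metabolism and of fast fibres were lower relative to other genes with construct 5. The oxidative phosphorylation score did not follow the macrophage score library by library: construct 5 replicate 2 had the highest macrophage score (1.12 above the control mean) and an oxidative phosphorylation score of -0.043, against -0.297 in replicate 1. The score of -0.043 in replicate 2 lay within the control range (-0.051 to 0.089). Replicate 2 also had a tricarboxylic acid cycle score of 0.04 and a fatty acid score of 0.289, each above every control (highest 0.023 and 0.127). The fast-fibre score was lowest in replicate 2 (-0.141, against 0.018 and 0.024 in replicates 1 and 3). Of the 41 oxidative phosphorylation genes, 39 had values below 0 and 0 passed (median -0.17, adjusted p = 2.59e-19; adjusted p = 0.85 with an estimated correlation). Cox4i1 went from 1063 ± 54.1 to 864 ± 86.3 FPKM (SD, n = 3; adjusted p = 0.0718), and Ndufv1 (-0.31) and Uqcrc1 (-0.35) had adjusted p-values of 0.0963 and 0.0977. The 22 tricarboxylic acid cycle and mitochondrial biogenesis genes had a median of -0.13 (adjusted p = 9.79e-08; adjusted p = 0.85 with an estimated correlation). Mdh2 (-0.28) lay below every control, and the regulators Tfam (0.22) and Ppargc1a (0.33) above every control. Idh3g (-0.29) had a lower mean, but construct 5 replicate 2 (106.02 FPKM) lay just above the lowest control (105.93 FPKM). Of this list 0 members passed. Glycolysis and glycogen genes had a median of -0.07 (adjusted p = 0.000113; adjusted p = 0.4 with an estimated correlation), and the muscle phosphoglycerate mutase Pgam2 had -0.42 (adjusted p = 0.0494; 0.056 with median-ratio scaling). Quantile normalization ended the call of this list (adjusted p = 0.354). Pfkfb1 (-0.50), Slc2a4 (-0.25) and Gpi1 (0.18) did not pass. Fast-fibre sarcomere genes had a median of -0.06 (adjusted p = 0.000181; adjusted p = 0.85 with an estimated correlation), with Tnni2 (-0.27), Tnnt3 (-0.24), Tpm1 (-0.25) and Mybpc2 (0.29) not passing. With quantile normalization the mean of that list relative to all genes turned to 0.03. Fatty acid genes had a median of -0.05 and a mean of 0.02, and their test was downward (adjusted p = 0.00377; adjusted p = 0.85 with an estimated correlation). Pdk4 had 0.87 (adjusted p = 0.134), Angptl4 0.59, Slc25a20 -0.23 and Mlycd 0.17.

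camera with a preset correlation of 0.01 thus called 14 of 33 lists with construct 5, 8 up and 6 down, and 0 with an estimated correlation (lowest adjusted p = 0.397, 1 list at an unadjusted p under 0.05). fry, which does not compare a list with other genes, called 4: histone acetyltransferase 1 and histone chaperones, ribosome biogenesis, atrophy genes and circadian clock genes. The 19 lists not called by camera, with adjusted p-values from 0.0832 to 0.885, were Schwann cell, denervation, calcium handling, erythroid, atrophy, endoplasmic reticulum stress, myogenic regulators, satellite cell, autophagy, heat shock, slow-fibre, circadian clock, p53 target, growth signalling, proliferation, adipocyte, N-degron, small RNA silencing and immediate early genes. Neutrophil and acute inflammation genes (3 measured), T and natural killer cell markers (1) and B and plasma cell markers (0) were too few to test. Median-ratio scaling ended the calls of the proteasome (adjusted p = 0.24), histone chaperone (0.0624), ribosomal protein (0.964, median 0.00) and ribosome biogenesis (0.337) lists. Quantile normalization ended those of the histone chaperone (0.0645), fast-fibre (0.689), endothelial (0.0524), glycolysis (0.354), fatty acid (0.549) and ribosome biogenesis (0.309) lists. With median-ratio scaling and without construct 5 replicate 1 the means of the proteasome and ribosomal protein lists relative to all genes both turned to -0.01, and as deposited without that library the mean of the fatty acid list turned to 0.02. Without control replicate 3 the proteasome (0.0845), histone chaperone (0.0519), ribosomal protein (0.551), ribosome biogenesis (0.0862) and interferon (0.0862) lists lost their calls, and without construct 5 replicate 1 so did the proteasome (0.0887), interferon (0.101), ribosomal protein (0.202), ribosome biogenesis (0.0887), endothelial (0.0887) and fatty acid (0.607) lists. Without construct 5 replicate 3 the proteasome (0.0749), ribosomal protein (0.107), ribosome biogenesis (0.117) and endothelial (0.262) calls ended, while the endothelial (0.363), fatty acid (0.0725) and ribosome biogenesis (0.0829) calls ended without control replicate 1. The endothelial call also ended without control replicate 2 (0.0644), and the ribosome biogenesis call without construct 7 replicate 2 (0.0522).

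**Figure D2:**
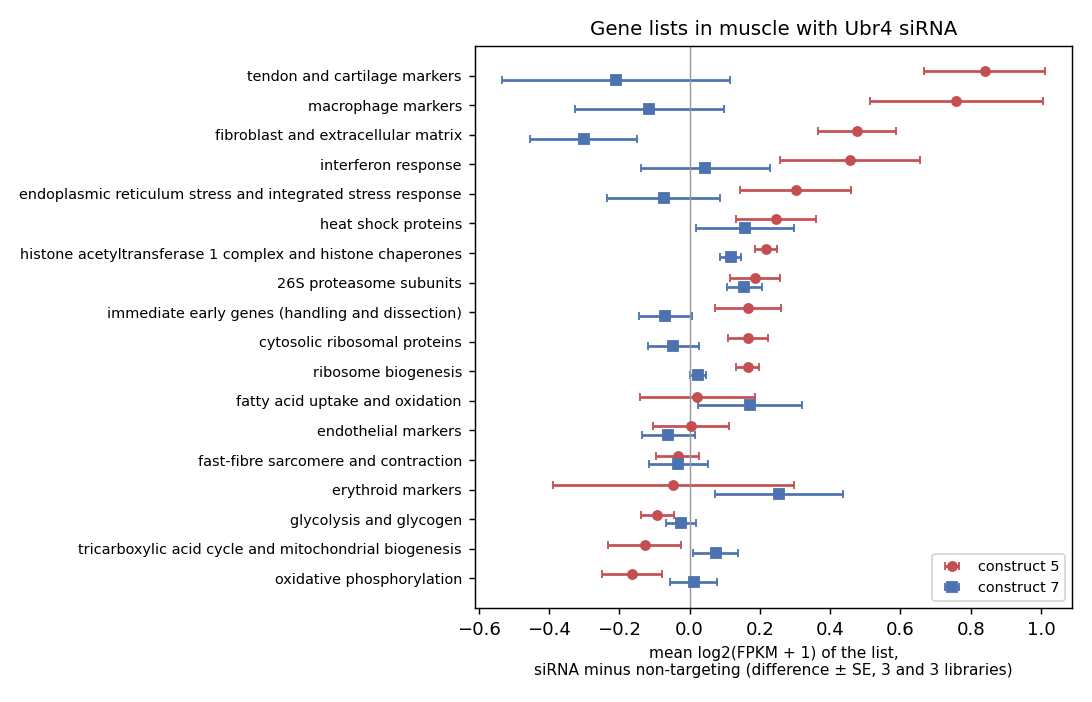
Difference of the mean log2(FPKM + 1) of each gene list between siRNA and control libraries (horizontal axis, points, with bars of 1 SE, 3 and 3 libraries), for the lists called by camera in any comparison. Macrophage markers lie at 0.76 with construct 5 and -0.12 with construct 7, and matrix genes at 0.48 and -0.30; 26S proteasome subunits lie at 0.19 and 0.16, without subtraction of the 0.13 shift of all genes with construct 5.

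The same question was asked of construct 7. Besides Ubr4, 5 genes fell: spermine oxidase, the dynein heavy chain Dync1h1, Arhgap10, the histone chaperone Anp32e and the DNA repair enzyme Parp1. Smox went from 91.4 ± 8.58 to 33.8 ± 4.71 FPKM (SD, n = 3; log2 change -1.41, adjusted p = 0.0277), and Dync1h1 from 11.4 ± 1.10 to 5.16 ± 0.844 FPKM (-1.02, adjusted p = 0.0277). Arhgap10 went from 16.4 ± 0.059 to 7.75 ± 1.58 FPKM (-1.01, adjusted p = 0.0277), Anp32e from 19.8 ± 0.868 to 12.1 ± 1.18 (-0.67, adjusted p = 0.0428) and Parp1 from 17.2 ± 0.949 to 11.6 ± 0.198 (-0.53, adjusted p = 0.0327). Each lay below the control range in 3 of 3 libraries. The genes with the smallest p among higher values were Obfc2a (1.06, adjusted p = 0.0912), Aldh3a1 (2.52, 0.12), Dhrs11 (0.46, 0.159), Tmem30a (0.37, 0.16) and Matr3 (0.36, 0.16), none of which passed.

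With construct 7 the matrix list was lower and the proteasome list higher relative to other genes, with 0 members of either passing the gene test. Of 26 matrix genes, 24 had values below 0 (median -0.27, adjusted p = 1.99e-09; adjusted p = 0.83 with an estimated correlation), 0 passed over all genes and 3 passed when adjusted over the list alone. The collagen cross-linking enzyme Lox had -0.66 (adjusted p = 0.0912), Col1a2 -0.53 (0.311), Thbs2 -0.39 (0.324), Col1a1 -0.59 (0.364), and the abundant Sparc -0.28 and Dcn -0.09. The matrix score was -0.54 and -0.279 in construct 7 replicates 1 and 3, below every control. In replicate 2 it was -0.084, within the control range (-0.099 to 0.148). The group difference of the matrix score was -0.301 (SE 0.152). Tendon and cartilage markers had a median of -0.20 (camera adjusted p = 0.0285, and 0.83 with an estimated correlation), with Comp at -0.42, Prg4 at -0.24, Chad at -0.59 and Fmod at -0.58, and the abundant Thbs4 at -0.12 and Cilp at 0.14. Their score was -0.565 and -0.446 in construct 7 replicates 1 and 3. In replicate 2 it was 0.382, above every control (-0.254 to 0.161). All 32 proteasome subunits had values above 0 (median 0.15, adjusted p = 3.78e-09; adjusted p = 0.83 with an estimated correlation), and 3 passed when adjusted over the list alone. Psma1 had 0.35 (adjusted p = 0.259), Psma2 0.27, Psmc6 0.29 and Psma5 0.31. The histone acetyltransferase 1 and histone chaperone list had a median of 0.09 with all 10 members above 0 (adjusted p = 0.0226; adjusted p = 0.83 with an estimated correlation). Rbbp4 had 0.31 (adjusted p = 0.278), Rbbp7 0.17 (0.476), Hat1 0.11 (0.753), Asf1a 0.13 and Hdac2 0.09, and 1 member passed when adjusted over the list alone. Fatty acid genes (median 0.17, adjusted p = 0.0243) and heat shock proteins (0.14, adjusted p = 0.0285) were higher relative to other genes. Ribosomal proteins (-0.05, adjusted p = 0.00201) and immediate early genes (-0.10, adjusted p = 0.0334) were lower, and each of these 4 lists had an adjusted p = 0.83 with an estimated correlation and 0 members passing. Examples were Hadhb (0.28), Acadl (0.29), Etfa (0.23) and Fabp3 (0.44), then Hsp90aa1 (0.63), Hspa4 (0.21), Hspa8 (0.25) and Dnaja1 (0.28). For the lower lists they were Rps25 (-0.28), Rpl7a (-0.20), Rps6 (-0.12) and Rpl38 (-0.15), then Ier3 (-0.26), Jund (-0.25), Klf2 (-0.17) and Egr1 (-0.42). Macrophage markers had a median of -0.12 (adjusted p = 0.0609) and oxidative phosphorylation genes of 0.00 (adjusted p = 0.765).

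limma called 6 of 10794 genes with construct 7, all lower; 1022 passed at an unadjusted p under 0.05, and voom called 6. After median-ratio scaling the calls were 5, and Anp32e had an adjusted p = 0.0637. The groups did not overlap in 1814 genes (16.8%), against 10% by chance. camera called 8 of 33 lists, 4 up and 4 down, with 0 called with an estimated correlation (lowest adjusted p = 0.832, 0 at an unadjusted p under 0.05) and 0 by fry (3 at an unadjusted p under 0.05). The other 25 lists had adjusted p-values from 0.0602 to 0.998. Without control replicate 2, control replicate 3 or construct 7 replicate 2 limma called 0 genes (854, 957 and 1032 at an unadjusted p under 0.05; voom was not run on these), and it called 1 without control replicate 1, 1 without construct 5 replicate 1, and 2 without construct 5 replicate 2 or replicate 3. The matrix and proteasome lists kept their calls in all 24 alternatives with the preset correlation; the tendon call ended without control replicate 1 (0.17), control replicate 2 (0.13), construct 7 replicate 1 (0.407) or replicate 3 (0.231). The histone chaperone call ended without construct 7 replicate 2 (0.0852), the fatty acid call without control replicate 3 (0.358) or construct 7 replicate 3 (0.683), and the ribosomal protein call without control replicate 2 (0.344) or construct 7 replicate 1 (0.453). The heat shock call ended without control replicate 3 (0.53) or construct 7 replicate 2 (0.0748) or replicate 3 (0.249), the immediate early call without control replicate 1 (0.365) or construct 7 replicate 1 (0.0512) or replicate 3 (0.0802). Median-ratio scaling ended the tendon (0.0684) and immediate early (0.0718) calls, and over all alternatives the highest adjusted p of the tendon list was 0.481.

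A further comparison asked what both constructs had in common. Ubr4, Smox and Anp32e were called lower with each construct. Anp32e went from 19.8 FPKM to 15.2 ± 1.24 (SD, n = 3) with construct 5 (log2 change -0.37, adjusted p = 0.0493) and to 12.1 with construct 7. These 3 genes compare with 0.036 expected for independent lists and with a median of 0 in 100 simulations in which unchanged groups shared the controls (1 simulation was as large). Ubr4 is the target of both siRNAs, so only Smox and Anp32e are informative here. The value for independent lists takes no account of the shared controls. The simulated groups held no changed genes, unlike construct 5 with 569 calls, so neither comparison matches the data. The count of genes called with both constructs was 1 without control replicate 1 and 0 without control replicate 2, control replicate 3, construct 5 replicate 1 or construct 7 replicate 2. In the mean of both constructs against the controls limma called 1 gene, Ubr4; 2066 passed at an unadjusted p under 0.05 and voom called 2. The count was 0 without control replicate 3 (Ubr4 adjusted p = 0.0677; 1778 genes at an unadjusted p under 0.05), 2 without control replicate 2 or construct 5 replicate 3, 3 without construct 5 replicate 2, 7 without construct 7 replicate 1 and 5 without construct 7 replicate 3. Smox (-1.23, adjusted p = 0.0536), Arhgap10 (-0.63, 0.0804), Anp32e (-0.52, 0.0804) and the oligosaccharyltransferase subunit Stt3b (-0.34, 0.0804) came closest among the lower genes. Among the higher genes those with the smallest p were Aldh3a1 (2.40), Obfc2a (0.92), Spon2 (0.45), the coat protein Copb1 (0.43) and Matr3 (0.37), each with an adjusted p = 0.0804. Arhgap10 (-0.75), Stt3b (0.34) and Spon2 (-0.7) were also called as differing between the constructs (construct 7 minus construct 5). For these genes the mean does not show an equal change with both constructs. Spon2 stood at 1.35, 1.47 and 1.37 FPKM with construct 7, against 1.34, 1.09 and 1.29 FPKM in the controls. All 6 siRNA libraries lay outside the control range in 1024 genes (9.5%), against 2.4% by chance.

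The proteasome list was higher relative to other genes in this comparison, with 0 members passing the gene test and all 32 values above 0 (median 0.16, adjusted p = 1.4e-05; adjusted p = 0.88 with an estimated correlation) and 9 passing when adjusted over the list alone. Of the 32 subunits, 29 lay above the median of all genes, which was 0.074 in this comparison. With median-ratio scaling camera still called the list in the mean (adjusted p = 0.001) but not with construct 5 alone (adjusted p = 0.24). In that scaling the score of construct 5 replicate 2 (-0.062) lay below every control (-0.043 to 0.069). Construct 7 replicate 1 (0.053) lay within the control range. A rise shared by both constructs was therefore not shown under that scaling. Psma1 had 0.36 (adjusted p = 0.0804), Psma2 0.28 (0.0821), Psmc6 0.33 (0.0821) and Psma5 0.35 (0.105). The histone acetyltransferase 1 and histone chaperone list had a median of 0.15 with all 10 members above 0 (adjusted p = 0.0078; adjusted p = 0.88 with an estimated correlation), and 2 passed when adjusted over the list alone. Rbbp4 had 0.34 (adjusted p = 0.0821), Rbbp7 0.24 (0.109), Ipo4 0.19, Hdac2 0.14 and Hat1 0.12 (0.403). The lists lower in the mean of both constructs were not shown to be lower with construct 7 alone, where oxidative phosphorylation had a median of 0.00 (adjusted p = 0.765), the tricarboxylic acid cycle 0.04 (0.259, upward), glycolysis -0.03 (0.22), fast-fibre genes -0.08 (0.0602) and endothelial markers -0.06 (0.152). Oxidative phosphorylation genes had a median of -0.08 in the mean (adjusted p = 3.84e-09), with Ndufv2 at -0.18, Cox4i1 at -0.15 and Ndufs3 at -0.14. Fast-fibre sarcomere genes were lower relative to other genes as well (-0.04, adjusted p = 0.000896), with Tnni2 at -0.25, Tnnt3 at -0.22, Acta1 at -0.24 and Tnnc2 at -0.20, although with quantile normalization that list's mean relative to all genes was 0.01. Glycolysis genes (-0.03, adjusted p = 0.00203; Pgam2 -0.33, Pfkfb1 -0.36, Pkm2 -0.16, Gpi1 0.18) were also lower. Tricarboxylic acid cycle genes (-0.06, adjusted p = 0.0078; Mdh2 and Idh3g -0.15, Tfam 0.18, Ppargc1a 0.41) and endothelial markers (-0.04, adjusted p = 0.0388; Eng -0.10, Tek 0.07, Emcn -0.05, Cldn5 -0.11, Cdh5 -0.05, Pecam1 -0.04) followed. With an estimated correlation these 5 lists had an adjusted p = 0.84 (glycolysis) or adjusted p = 0.88 (the others). The 0 members passing in any of the 7 lists called by camera stand beside 2066 genes at an unadjusted p under 0.05; fry called 2 lists, histone chaperones and circadian clock genes. The endothelial call ended without control replicate 1 (0.447), control replicate 2 (0.084), construct 5 replicate 1 (0.106) or replicate 3 (0.123) or construct 7 replicate 1 (0.0852), the tricarboxylic acid cycle call without construct 5 replicate 1 (0.194) and the glycolysis call without control replicate 2 (0.082). Quantile normalization ended the fast-fibre (0.797), tricarboxylic acid cycle (0.203) and glycolysis (0.373) calls.

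Across the 10794 genes, log2 changes with both constructs had a Pearson correlation of 0.364, and 65.7% of genes had the same sign. Unchanged groups that shared the controls gave a median correlation of 0.622 (95% of simulations from -0.316 to 0.94) and 70.2% with the same sign. Neither observed value exceeded the simulated median. The covariance of 0.013 exceeded the simulated median of 0.00891 by 0.00406, and 38 of 100 simulations were as large. The simulated groups held no changed genes and so do not match the data. These comparisons therefore do not decide whether the constructs share effects. Genes are not independent replicates, and 3 controls cannot be split into separate sets of at least 2 libraries. The correlation was 0.477 without control replicate 2 and 0.135 without construct 7 replicate 2.

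**Figure D3:**
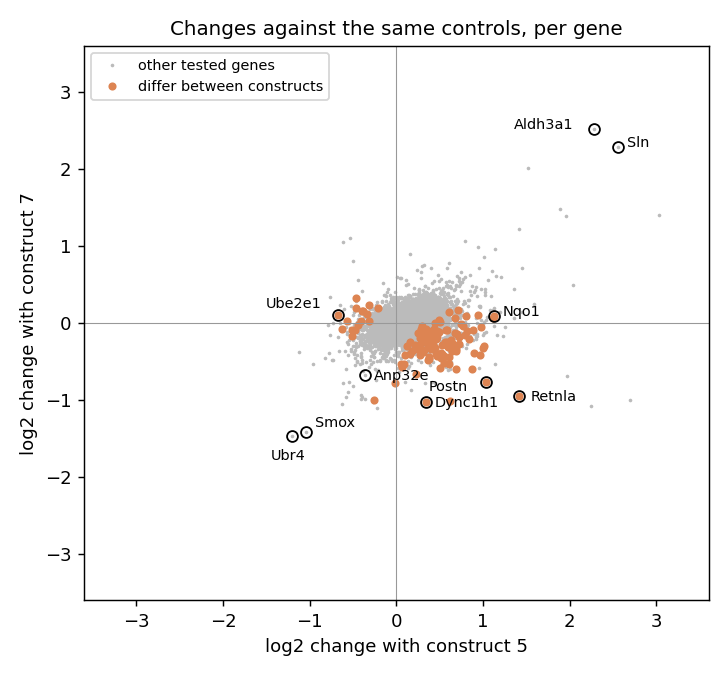
Log2 change of each of 10794 tested genes with construct 5 (horizontal axis) and with construct 7 (vertical axis) against the same 3 controls; orange points are the 132 genes that differed between the constructs, and circles mark 10 genes named in the text. Ubr4 and Smox lie at the lower left, whereas Ube2e1 (-0.68 with construct 5), Nqo1, Postn, Retnla and Dync1h1 (-1.02 with construct 7) differ between the constructs.

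The last comparison tested whether both constructs had different effects. Ube2e1 stood at 14.4 ± 0.454 FPKM (SD, n = 3) with construct 7 against 7.98 with construct 5, a log2 difference (construct 7 minus construct 5) of 0.78 (SE 0.057, adjusted p = 0.00178) whose call held in all 24 alternatives. The coat protein Sec23a (0.79, adjusted p = 0.0195), the trafficking factor Trappc1 (0.65, 0.0199), Tulp4 (0.55, 0.0336) and the kinesin heavy chain Kif5b (0.55, 0.0336) were also higher with construct 7. Dync1h1 (-1.36, adjusted p = 0.00416), Parp1 (-0.58, 0.0119) and Arhgap10 (-0.75, 0.0256), which fell with construct 7, stood at 14.7, 17.9 and 13.6 FPKM with construct 5. Retnla (-2.37, adjusted p = 0.0475), periostin (Postn, -1.79, 0.0488), Cthrc1 (-1.63, 0.0195), fibronectin (Fn1, -1.47, 0.0345) and Comp (-1.38, 0.0195) were lower with construct 7 than with construct 5. Each of these genes had groups that did not overlap. With median-ratio scaling Retnla (adjusted p = 0.0687), Postn (0.0745) and Fn1 (0.0582) did not pass. No difference was shown for Smox (-0.37, adjusted p = 0.221), Anp32e (-0.30, 0.101), Sln (-0.27, 0.797), Rbbp4 (-0.05, 0.694), Rbbp7 (-0.14, 0.245) or Hat1 (-0.02, 0.884), and the signs for Rbbp4 and Hat1 turned positive with median-ratio scaling and with quantile normalization.

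Matrix, macrophage and tendon genes separated the constructs as groups. All 26 matrix genes had values below 0 for construct 7 minus construct 5 (median -0.76, camera adjusted p = 9.66e-13; adjusted p = 0.56 with an estimated correlation), 10 passed over all genes and 22 when adjusted over the list alone. Lox had -0.88 (adjusted p = 0.0119), Thbs2 -0.91 (0.015), Col1a2 -1.14 (0.0174) and Col1a1 -1.28 (0.0201). All 18 macrophage markers had values below 0 (median -0.88, adjusted p = 1.05e-07; adjusted p = 0.63 with an estimated correlation), 3 passed, namely Lyz2 (-1.29), Cd14 (-0.67) and Gpnmb (-1.03), Tyrobp had -1.09 (0.059), and 15 passed when adjusted over the list alone. All 10 tendon and cartilage markers had values below 0 (median -1.08, adjusted p = 3.28e-06; adjusted p = 0.57 with an estimated correlation), 3 passed, namely Comp, Kera (-1.06) and Prg4 (-0.60), Fmod had -1.54 (0.0525), and 8 passed when adjusted over the list alone. With median-ratio scaling 5 matrix, 1 macrophage and 1 tendon gene passed, without Cd14 (adjusted p = 0.0697), Gpnmb (0.0681), Kera (0.0564) and Prg4 (0.0665). Endothelial markers had a median of -0.06 (adjusted p = 0.365). Interferon genes (median -0.40, adjusted p = 0.00523), endoplasmic reticulum stress genes (-0.38, adjusted p = 0.00523; 12 of 21 when adjusted over the list alone), ribosomal proteins (-0.20, adjusted p = 3.64e-07; 6 of 50) and ribosome biogenesis genes (-0.15, adjusted p = 0.0312) were lower relative to other genes too. Each of these 4 had an adjusted p = 0.85 with an estimated correlation and 0 members passing. Their members with the smallest p were Psmb9 (-0.36), Xaf1 (-0.39), Irf9 (-0.35) and Stat2 (-0.50), then Manf (-0.56), Asns (-0.75), Hsp90b1 (-0.34) and Sdf2l1 (-0.80). For the ribosome they were Rpl7a (-0.35), Rps25 (-0.45), Rps23 (-0.28) and Rps16 (-0.28), then Npm1 (-0.31), Nop58 (-0.24), Rrs1 (-0.21) and Gnl3 (-0.27).

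Lists of energy metabolism were higher relative to other genes with construct 7 than with construct 5, although construct 5 replicate 2 (oxidative phosphorylation score -0.043) lay within the range of construct 7 (-0.052 to 0.11). All 41 oxidative phosphorylation genes had values above 0 and 0 passed (median 0.19, adjusted p = 8.88e-21; adjusted p = 0.56 with an estimated correlation), with Atp5b at 0.33 (adjusted p = 0.0867), Sdha at 0.38, Cox4i1 at 0.31 and Atp5a1 at 0.36. Tricarboxylic acid cycle genes had a median of 0.22 (adjusted p = 6.13e-13; adjusted p = 0.56 with an estimated correlation), with Ogdh at 0.38, Fh1 at 0.28 and Idh3g at 0.27. Fatty acid genes had a median of 0.22 (adjusted p = 8.37e-09; adjusted p = 0.63 with an estimated correlation), with Slc25a20 at 0.50, Hadhb and Hadha at 0.30 and Acadvl at 0.35. Construct 5 replicate 2 lay within the construct 7 range for the fatty acid score (0.289, against -0.001, 0.097 and 0.417). The same held for its tricarboxylic acid cycle score (0.04, against 0.032, -0.011 and 0.2). The score differences between the constructs were 0.149 (SE 0.191) and 0.202 (SE 0.121). Glycolysis genes had a median of 0.04 (adjusted p = 0.00124; adjusted p = 0.56 with an estimated correlation), with Slc2a4 at 0.29, Ldhb at 0.75, Pgam2 at 0.19 and Gys1 at 0.27. The 5 erythroid markers had a median of 0.36 (adjusted p = 0.00523; adjusted p = 0.63 with an estimated correlation), with Hba-a2 at 0.41 and Hba-a1, Hbb-b1 and Hbb-b2 at 0.35 to 0.36. The erythroid scores of the groups overlapped, with a difference of 0.301 (SE 0.305). Construct 5 replicate 2 had the highest score of all libraries (0.535, against 0.158 to 0.383 with construct 7), while replicates 1 and 3 had -0.219 and -0.453. Fast-fibre genes had a median of -0.02, a mean of 0.00 and an upward test relative to all genes (adjusted p = 0.0312; adjusted p = 0.85 with an estimated correlation), which turned downward with quantile normalization. Cacna1s had 0.35, Myh2 0.54, Mybpc2 -0.28 and Acta1 -0.21, and 0 members of these 6 lists passed the gene test.

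limma called 132 genes in this comparison, 16 higher and 116 lower with construct 7; 2491 passed at an unadjusted p under 0.05, and voom called 185. The groups did not overlap in 2744 genes (25.4%), against 10% by chance. After median-ratio scaling the calls were 79, of which 38 were higher and 41 lower and 57 were among the 132. camera called 13 of 33 lists, 6 up and 7 down, with 0 called with an estimated correlation (lowest adjusted p = 0.558, 2 at an unadjusted p under 0.05) and 5 called by fry. The count of genes was 55, 53 and 52 without control replicates 1, 2 and 3, 17 without construct 5 replicate 1, 38 without construct 5 replicate 2, 3 without construct 7 replicate 1, 387 without construct 7 replicate 2 and 4 without construct 7 replicate 3. The macrophage, matrix, tendon, oxidative phosphorylation, tricarboxylic acid cycle and fatty acid lists kept their calls in all alternatives with the preset correlation; those of the glycolysis and ribosomal protein lists ended in other alternatives (highest adjusted p 0.714 and 0.242). Median-ratio scaling ended the fast-fibre (0.0668) and ribosome biogenesis (0.314) calls, and quantile normalization ended those of the fast-fibre (0.186), erythroid (0.183), glycolysis (0.714) and ribosome biogenesis (0.246) lists. The fast-fibre call ended without construct 5 replicate 2 (0.604), construct 7 replicate 1 (0.159) or replicate 2 (0.426), the interferon call without construct 5 replicate 1 (0.0677) or construct 7 replicate 1 (0.141), and the erythroid call without construct 5 replicate 3 (0.0674). The ribosome biogenesis call ended without construct 5 replicate 1 (0.0699) or replicate 3 (0.128) or construct 7 replicate 1 (0.159) or replicate 2 (0.0612), and the endoplasmic reticulum stress call without construct 5 replicate 2 (0.0635).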

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

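The tests in this part were chosen after the results were seen.

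Several values were singled out because limma's test of construct 7 minus construct 5 found a difference between groups. They are the count of 132 genes and the log2 differences of Nqo1 (-1.03), Kera (-1.06), Ube2e1 (0.78), Tulp4 (0.55), Gpnmb (-1.03), Lyz2 (-1.29), Thbs2 (-0.91), Col1a2 (-1.14), Col1a1 (-1.28), Comp (-1.38), Dync1h1 (-1.36), Arhgap10 (-0.75) and Parp1 (-0.58). The others were Lox (-0.88), Prg4 (-0.6), Spon2 (-0.7), Stt3b (0.34), Sec23a (0.79), Trappc1 (0.65), Kif5b (0.55), Retnla (-2.37), Postn (-1.79), Cthrc1 (-1.63), Fn1 (-1.47) and Cd14 (-0.67). Lists were singled out in the same way by camera, with mean differences relative to all genes of 0.12 for fast-fibre, -0.3 for interferon, -0.76 for macrophage, -0.66 for matrix, -0.93 for tendon and 0.42 for erythroid genes. Those of oxidative phosphorylation (0.29), the tricarboxylic acid cycle (0.32), glycolysis (0.18), fatty acids (0.26), ribosomal proteins (-0.1), ribosome biogenesis (-0.03) and endoplasmic reticulum stress (-0.26) complete the set.

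More genes were called higher than lower with construct 5. Under median-ratio scaling 17.9% of the calls were higher, but that scaling sets the median change to about 0, so this test is void and does not tell whether scaling was the cause. A shift from construct 5 replicate 1 alone was argued against, since the median change of all genes was still 0.11 without that library. Which scaling is right cannot be settled from FPKM, so the direction of small changes with construct 5 stays open.

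Macrophage and matrix genes were higher with construct 5 than with construct 7. A lower share of muscle fibre RNA that raises every other cell type alike was argued against, because the macrophage minus endothelial score differed by -0.81 (SE 0.191) between the constructs. The matrix difference was -0.78 with all libraries and -0.83 without construct 5 replicate 1. That library had the lowest matrix score of construct 5 (0.371, against 0.634 and 0.422), so leaving it out could only widen the difference. The scores themselves show that the matrix difference did not come from that library alone. Under median-ratio scaling the list with the smaller difference, the matrix list, had -0.67. The median difference of all genes was only -0.099 as deposited, so this rescaling could not have removed a difference of that size. More macrophages and fibroblasts in the sampled tissue, or effects of an siRNA on genes other than Ubr4, could each give this pattern and were not tested.

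Splits of the libraries into other groups were counted as well. The real grouping was the only 1 of the 10 splits with a count as large for 569 genes with construct 5, for 78 under median-ratio scaling, for 6 with construct 7 and for 132 between the constructs, the highest other count being 0 each time; 10 splits are too few to tell. For the mean of both constructs, 12 of 100 splits, the real one included, called at least 1 gene and the highest other count was 155. Chance was therefore not excluded for that count, and at least 1 other split of the samples separated more genes than the real one did. Other splits can set construct 5 libraries against the rest, however, so they can carry the difference between the constructs and do not measure chance alone. The gene called in the real grouping was Ubr4, the target of both siRNAs.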

How the results depend on the processing

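Limits included 3 libraries per group, scaling, shared controls and the correlation between genes of a list. Tests in the added settings were chosen after the results were seen. Of the list values 876 stayed the same, 117 were weaker, 0 stronger and 3 reversed; of the named gene values 4712 stayed the same, 797 were weaker, 77 stronger and 58 reversed. The cause was not tested.

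Numbers of called genes are given for construct 5 (569), construct 7 (6), the mean of both (1) and the difference (132) in this order. A pseudocount of 0.1 gave 316 for construct 5. No filter gave 5, 0, 0 and 10 (5054, 1511, 2841 and 3986 at an unadjusted p under 0.05 in limma; voom was not run without a filter), and a filter at 5 FPKM gave 204 for construct 5, 2 for the mean and 48 for the difference. Median-ratio scaling gave 78 for construct 5 and 79 for the difference, quantile normalization 86 and 58, and totals of 1000000 gave 1024 for construct 5 and 2 for the mean. The 6 libraries alone gave 246 for construct 5, 2 for construct 7 and 23 for the difference. Weights per library gave 103 for the mean and 201 for the difference. voom gave 2 for the mean, and voom with median-ratio scaling 145 for construct 5. Median-ratio scaling without construct 5 replicate 1 gave 4 for construct 5 and 20 for the difference; without construct 7 replicate 1 it gave 113 for construct 5, 4 for the mean and 2 for the difference. Leaving out 1 library gave 1 to 581, 0 to 5, 0 to 7 and 3 to 387.

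The replicate block gave 11 for construct 5, 4 for the mean and 217 for the difference. The labels do not say whether replicate numbers pair samples. Same-number correlations of deviations from the group means ran from -0.364 to 0.313, 2 of 9 over 0.1. Of the 9 libraries, 2 correlated best with their own number. These values show no clear pairing, but with 3 libraries per group they cannot exclude it, so the block result stands as an alternative.

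Genes called with both constructs (3) were 0 with no filter, 1 with median-ratio scaling without construct 5 replicate 1, and 0 to 4 with 1 library left out. The correlation of fold changes between the constructs, over all tested genes, was 0.327 to 0.454 in other settings and 0.135 to 0.477 with 1 library left out. Lists called with construct 5 (14) were 0 with an estimated correlation and 8 to 16 with 1 library left out. Lists called with construct 7 (8) were 5 with a filter at 5 FPKM, 13 with weights, 0 with an estimated correlation and 4 to 13 with 1 library left out. Lists called with the mean (7) were 16 with no filter, 11 with voom and median-ratio scaling, 13 with median-ratio scaling without construct 7 replicate 1, 0 with an estimated correlation and 5 to 11 with 1 library left out. Ubr4 with no filter had an adjusted p = 0.0523 with construct 5 (-1.20) and 0.0976 with construct 7 (-1.47); with 1 library left out its log2 change was -1.293 to -1.090 and -1.560 to -1.383.

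Directions of tests or log2 changes reversed for these values. Median-ratio scaling: Egfl7 -0.017, Ramp2 -0.06 and Pecam1 -0.138 with construct 5; Tek -0.007 with the mean; Hat1 0.078 and Rbbp4 0.054 between constructs. Quantile normalization: fast-fibre genes 0.034, Ramp2 -0.083, Hat1 -0.016 and Pecam1 -0.071 with construct 5; Tek -0.014 with the mean; fast-fibre genes -0.051, Hat1 0.101 and Rbbp4 0.056 between constructs. Totals of 1000000: Cdh5 0.023 with construct 5, Pecam1 0 with the mean. Weights: Pecam1 -0.019 with construct 5, Hat1 0.007 between constructs. voom with median-ratio scaling: Egfl7 -0.013, Ramp2 -0.061 and Pecam1 -0.145 with construct 5, Tek -0.008 with the mean, Hat1 0.091 and Rbbp4 0.062 between constructs. Median-ratio scaling without construct 5 replicate 1: ribosomal proteins -0.009, Egfl7 -0.002, Ramp2 -0.077 and Pecam1 -0.134 with construct 5, Hat1 0.078 and Rbbp4 0.056 between constructs. Median-ratio scaling without construct 7 replicate 1: Egfl7 -0.017, Ramp2 -0.06 and Pecam1 -0.138 with construct 5, Thbs4 0.064 with construct 7, Tek -0.046 with the mean, Acta1 0.006, Hat1 0.119 and Rbbp4 0.108 between constructs. List means relative to all genes also changed sign while the direction of the test did not: with construct 5, ribosomal proteins at -0.004 with a pseudocount of 0.1, -0.011 with voom and -0.01 with voom and median-ratio scaling, and 26S proteasome subunits at -0.009 with median-ratio scaling without construct 5 replicate 1; with the mean, fast-fibre genes at 0.009 with quantile normalization.

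With 1 library left out, these ranges crossed or reached 0: the list means relative to all genes of fatty acid (-0.232 to 0.018) and ribosomal protein (-0.007 to 0.076) genes with construct 5, and the log2 changes of Egfl7 -0.032 to 0.299 with construct 5, Ramp2 -0.001 to 0.17 with construct 5, Dcn -0.01 to 0.318 with construct 5, Cdh5 -0.16 to 0.054 with construct 5, Pecam1 -0.115 to 0.106 with construct 5, Dcn -0.161 to 0.026 with construct 7, Thbs4 -0.449 to 0.086 with construct 7, Cilp -0.516 to 0.724 with construct 7, Tek -0.007 to 0.113 with the mean, Emcn -0.124 to 0.04 with the mean, Cldn5 -0.387 to 0.028 with the mean, Cdh5 -0.116 to 0.004 with the mean, Pecam1 -0.16 to 0.054 with the mean, Hat1 -0.09 to 0.018 between constructs.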

Other observations

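Some groups of genes had not been described above. Denervation genes had a median log2 change of 0.57 with construct 5 (camera adjusted p = 0.144) and 0.22 with construct 7 (0.0678), and 7 of 13 passed with construct 5 when adjusted over the list alone. Myogenic regulators and embryonic sarcomere genes had a median of 0.72 with construct 5 (camera adjusted p = 0.35), and slow-fibre genes 0.39 (0.641). With median-ratio scaling the denervation (0.0187) and myogenic (0.0194) lists passed with construct 5, and without that scaling each had an adjusted p = 0.85 with an estimated correlation. Circadian clock genes passed fry with construct 5 (adjusted p = 0.00298) and with the mean of both constructs (0.011), but not camera (0.677 with construct 5). Because fry does not compare a list with other genes, the shift of all genes enters its result. With median-ratio scaling the circadian median fell from 0.215 to 0.094 with construct 5 and from 0.097 to 0.012 in the mean.

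The NRF2 tests below were written down before they were run but after the values of their 4 genes had been seen, so these genes were chosen after their values were seen. The transcription factor NRF2 (Nfe2l2) drives detoxifying genes. Nfe2l2 rose with construct 5 (0.48, limma adjusted p = 0.0344) and had 0.29 (0.278) with construct 7; Gsr had 0.62 (0.0406) and 0.45 (0.278). The hypothesis was that Ubr4 siRNA raises NRF2 targets. In the 24 measured targets not seen before, the mean change with both constructs was 0.219 against 0.074 for all genes, with 22 above 0. Construct 5 carried most of this: its mean was 0.341, against 0.097 with construct 7, where 16 of the 24 were above 0. camera with the preset correlation gave p = 0.06784 for these 24 targets with construct 7. Nqo1 had 0.10 there (limma adjusted p = 0.908). For the difference between constructs camera gave p = 0.01371 over the 24 targets with the preset correlation and p = 0.2314 with an estimated correlation. For the mean of both constructs camera gave p = 0.001014 with the preset correlation and p = 0.1261 with an estimated correlation, so the test was not passed and the question stays open. A single low control library was argued against for the mean of the 4 genes only, which was 0.982 and at lowest 0.94 without one control. Aldh3a1 (2.397) carried most of that mean, against 0.384 for Nfe2l2, 0.611 for Nqo1 and 0.538 for Gsr. Its stability therefore says little about the other genes or about NRF2 targets as a group.

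Another hypothesis is that Smox and Anp32e respond to loss of Ubr4, since both fell with each construct; the call of Anp32e with construct 7 ended under median-ratio scaling (adjusted p = 0.0637), so it might be the less certain of both. Restoring Ubr4 by a transcript that resists the siRNA, with Smox measured by quantitative PCR, would test this. One more is that Ube2e1 with construct 5 and Dync1h1 and Parp1 with construct 7 could be effects of single siRNAs on genes other than Ubr4, as each differed between the constructs; under median-ratio scaling Ube2e1 had -0.81 with construct 5. Arhgap10 also differed between the constructs (-0.75), so it could be such an effect of construct 7 as well. It lay below every control with construct 5 too (13.6 against 16.4 FPKM). That is weak ground for setting it apart, since 38.2% of tested genes did not overlap with the controls there. A search of the transcripts of Ube2e1, Dync1h1, Parp1 and Arhgap10 for matches to the siRNA seeds, and another construct, would test this hypothesis.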
